A study of Mus musculus with 8 samples.

How the data were processed

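Gene expression was measured in whole-skin biopsies of wound scars from mice, taken at an early stage after wounding, on Affymetrix Exon arrays. The labels place 8 arrays in 2 groups of 4, a strain with a low level of hair regeneration and a strain with a high level. The design text says that each group held 4 mice, so the arrays of a group were taken as separate animals. Neither the strain names nor the day of the biopsy are given in the sources used here. Total RNA was extracted from biopsies stored in RNAlater, amplified with random primers and labelled with biotin, per the labels' protocols.

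The deposited values are log2 expression values per transcript cluster, the unit of the array that gathers the probes of a transcribed locus. Affymetrix Expression Console and PLIER, a method that combines the probes of a set into a single value, are named in the submitters' processing notes, with no version. The background correction and the normalization between arrays are not given in the sources used here. The deposited file holds 115830 rows and a column per array. Its values run from 2.10 to 14.92, and the array medians lie between 6.09 and 6.29. A scanner signal has such a range only after a log2 transformation, so the values were used as they are. The largest difference between array medians was under the limit of 0.5 set for centring, so none was applied. No detection calls were used, and low values can hold background. For arrays the number of arrays limits the precision, and here that is 4 per group.

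Rows were named through the platform annotation. It pairs 25539 rows with 1 gene symbol and 2300 rows with several, and it lists no gene for 87991 rows. Rows with several genes were left out of the gene-level tests, which removes many near-identical family members, and rows of related genes that stayed can still share signal between paralogs. Of the rows with 1 symbol, 24941 matched a gene of the GRCm38.p6 reference by Entrez number, and 0 symbols changed. The reference was used only for names and for which genes neighbour each other. Several rows of a gene were averaged on the log2 scale, which concerned 3109 of the 20259 genes tested. No filter on low values was applied.

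The main comparison was high minus low regeneration in limma 3.58.1 under R 4.3.3 (lmFit and eBayes without a trend, two-sided), with version 1.17.8 of data.table for reading. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Gene lists of pathways, cell types and technical signs were fixed before the data were examined, as were the rule for named genes and the first set of alternatives below, and 35 of them with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. Confidence intervals of list medians are 95% bootstrap intervals over the members from 10000 draws, and from 2000 draws in the added settings. An exact permutation test of each list's mean per array was added after the data were seen, and its p-values were adjusted over the lists.

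The genes named in the text follow a rule. It takes the 12 largest called changes in each direction whose groups do not overlap, leaving out predicted gene models. It adds up to 4 members with the smallest p of each list that passed its test or held a called member, and candidate genes that published work of the laboratory behind this series on the same wound model has concerned. Members that the rule names but that did not pass are given only in the counts of their list. Genes outside the rule are named as such where they appear. Of 15 candidates 1 is not reported here. The candidates and the list of double-stranded RNA sensing come from that work and are not independent evidence of its direction.

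The comparison was tested on simulated data, drawn for the 20259 genes from their means and residual SDs with 200 genes changed. It recovered 62.7% of the genes changed by 0.5 on the log2 scale, 98.5% of those changed by 1 and 95.5% of those changed by 2, and 14 of its 185 calls were unchanged genes. In simulated lists, the list that was shifted was called and 0 of the others. The simulated genes varied independently of each other. The simulation therefore does not show how often lists are falsely called when their members vary together.

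The alternatives were the replicate number as a block, quantile normalization, median centring, cyclic loess, eBayes with a trend or robust, array weights, filters at the median and at the 25th percentile of gene level, the brightest row or the median row of a gene, all rows of the table, other thresholds and leaving out each array in turn. Further settings were added after the data were seen. They left out low 3 and low 4, which were rich in muscle transcripts, or left out the arrays with Y-linked signal, low 2, low 4 and high 4, or used the mean of the muscle list or the Xist level as a covariate.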

Results

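Wound-induced hair neogenesis is the formation of new hair follicles in the scar of a large skin wound in adult mice. The study compared early wound scars of a mouse strain with low regeneration and a strain with high regeneration, 4 mice each, by exon array. The question was which transcripts differ between the scars of strains that regenerate hair follicles to different degrees. The 8 arrays had log2 medians between 6.09 and 6.29, and their number limits the precision. Arrays correlated across all rows at r of 0.968 to 0.977 within the low group, 0.975 to 0.980 within the high group and 0.959 to 0.975 between groups. Rows are not independent replicates, so these values only describe the arrays. The first principal component of the gene values held 43.8% of the variance and the second 20.4%.

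In the high-regeneration scars 22 of 27 interferon-stimulated genes were higher. Lower were 19 of 38 genes of the hair shaft and inner root sheath, 12 of 18 of pigment cells, 7 of 16 of the sebaceous gland and 16 of 36 of the cell cycle, while 0 lists passed with an estimated correlation between genes (adjusted p of 0.155 to 0.217 for these 5). Of 20259 genes, 376 were higher and 500 were lower in high regeneration (limma, adjusted p under 0.05), and 4420 had an unadjusted p under 0.05. A log2 change of at least 1 was reached by 43 of the higher and 69 of the lower genes. Several rows were averaged in 120 called genes, and in 10 of these the rows had opposite signs. In 874 of the 876 called genes the groups did not overlap. This held for 14.5% of all genes, against 2.86% by chance. Calls were 42.9% higher genes. The share was 26.3% after median centring (212 higher and 593 lower) and 31.7% after cyclic loess (291 higher and 628 lower). The counts also depended on single arrays. Higher and lower genes numbered 130 and 171 without low 2, 195 and 276 without low 3, 166 and 215 without low 4, 231 and 287 without high 1, 213 and 302 without high 2, 129 and 163 without high 3, and 168 and 226 without high 4. Without low 1 they were 536 and 669.

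Some arrays stood apart within their group. The skeletal muscle list had mean log2 values of 8.95 in low 3 and 9.67 in low 4, against 6.72 to 6.89 in the other arrays. Xist, the RNA of the inactive X chromosome in females, lay at 12.84 ± 0.08 (SD) in 5 arrays, at 6.11 in high 4, and between these levels in low 2 (9.60) and low 4 (10.05). The Y-linked gene Eif2s3y lay at 7.67 in low 2, 7.57 in low 4 and 7.70 in high 4, against a mean of 4.28 ± 0.28 in the 5 others. Without low 3 and low 4, 127 genes were higher and 198 lower. Without low 2, low 4 and high 4, which leaves 2 and 3 arrays, 5 were higher and 10 lower. With the Xist level as a covariate 254 were higher and 357 lower.

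**Figure D1:**
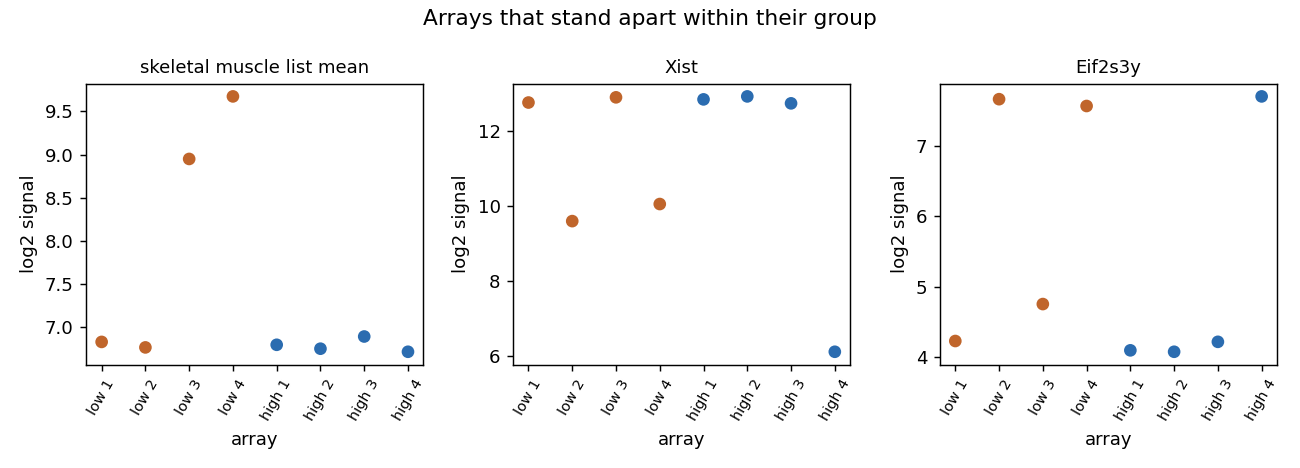
Log2 signal in each of the 8 arrays of the mean of the skeletal muscle list, of Xist and of Eif2s3y, a point per array, with low regeneration in orange and high regeneration in blue. The muscle list mean is 8.95 in low 3 and 9.67 in low 4 and at most 6.89 elsewhere, and Xist is intermediate in low 2 (9.60) and low 4 (10.05).

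The largest rises were in genes of the cornified envelope, the protein layer that seals the outer epidermis. Sprr2f, a small proline-rich envelope protein, was 2.96 ± 0.41 (SE) higher on the log2 scale (adjusted p = 0.00848), from 5.84 ± 0.44 (SD, n = 4) to 8.81 ± 0.92. Sprr2e was 2.13 ± 0.40 higher and Sprr2g 4.28-fold higher, with the pseudogene Sprr2j-ps at 2.54. Lce3f and Lce3c, late cornified envelope genes, were 1.88 and 1.63 higher, the latter at an adjusted p of 0.0492 (0.0244 to 0.347 over the alternatives, and above the threshold whenever an array other than low 1 was left out). These families are close paralogs, and which member gave the signal is uncertain. The other genes among the 12 largest rises were the interferon-induced genes Ifit1 (1.97), Slfn4 (1.66) and Usp18 (3.03-fold), together with Fibin (1.94), Kera (1.80), a proteoglycan core protein, and Tmprss11b (1.76), a membrane-bound serine protease.

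The 12 largest falls included hair and pigment genes. Dct and Tyrp1, enzymes of melanin synthesis, fell by 2.73 ± 0.35 and 2.14 ± 0.25 (SE). Dsg4, a desmosomal cadherin of the hair shaft, fell by 2.69 ± 0.32 (adjusted p = 0.00517), from 9.90 ± 0.56 (SD, n = 4) to 7.21 ± 0.56. Inner root sheath and hair keratins were among the 12, with Krt73 at -2.37, Krt35 at -2.09, Krt28 at -2.08 and Krt25 at -2.06, beside the keratin-associated protein Krtap24-1 at -2.13. Serpina3b, of the family of serine protease inhibitors, fell by 2.48. Retnla, a secreted product of alternatively activated macrophages, fell by 2.41 ± 0.57 at an adjusted p of 0.0484 (0.0137 to 0.395 over the alternatives, and above the threshold whenever an array other than low 1 was left out). It was highest in the muscle-rich low 3 (8.74) and low 4 (7.47). Low 2 was at 6.90 and low 1 at 5.57, against 4.49 to 5.49 in the high arrays. D17H6S56E-5 and AI506816 had changes of -2.85 and -2.82. Each had 3 rows that disagreed in size, from -4.25 to -0.28 and from -5.15 to -0.0044. Without low 3 and low 4, 14 of these 24 genes still passed, and leaving out a single array left between 17 (without low 2 or high 4) and 23 (without low 1).

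**Figure D2:**
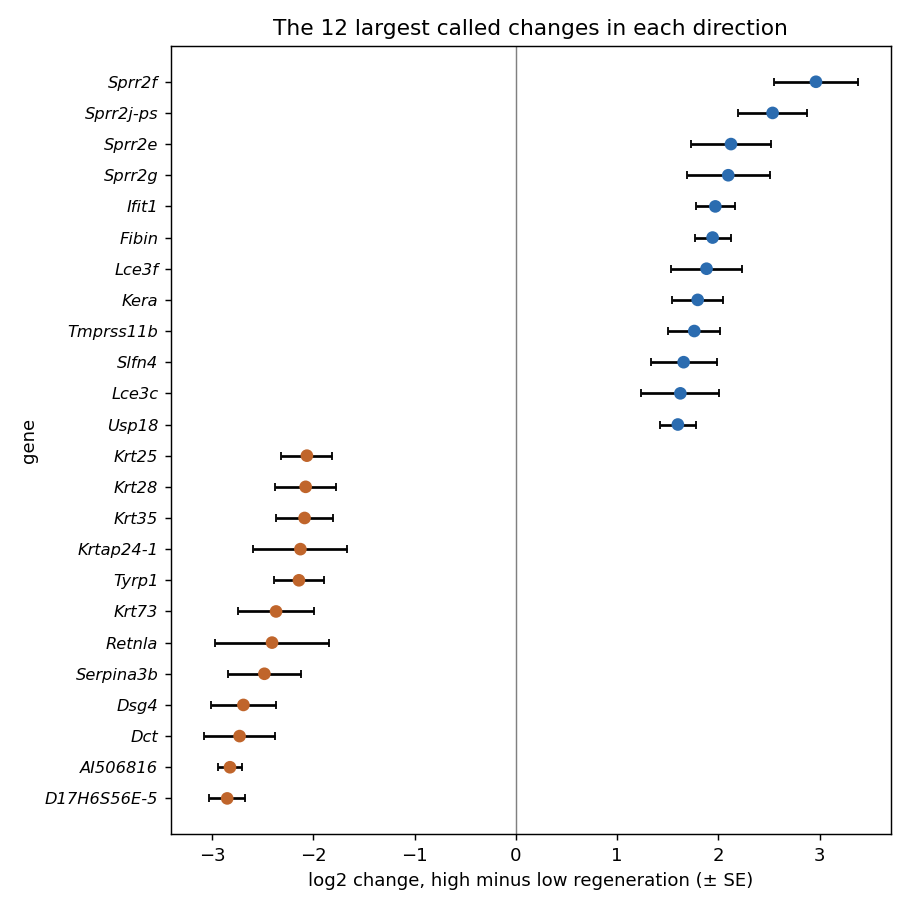
Log2 change, high minus low regeneration, of the 12 largest called changes in each direction, as points with their standard error from limma (4 arrays per group), positive in blue and negative in orange. The changes run from -2.85 in D17H6S56E-5 to 2.96 in Sprr2f.

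Interferon-stimulated genes rose together. Of 27 measured members 22 rose, 0 fell and all 27 had positive estimates, with a median of 0.84 on the log2 scale (95% interval 0.70 to 0.96) and 24 risers adjusted over the list alone. Ifit1 was at 8.97 ± 0.46 (SD, n = 4) in low and 10.94 ± 0.12 in high regeneration. Ifit3 was 1.55 ± 0.12 (SE) higher (adjusted p = 0.00101), Mx2 1.14 ± 0.11 and Xaf1 0.92 ± 0.09. Camera gave an adjusted p of 1.6e-25, and with an estimated correlation the adjusted p = 0.155. The median was 0.72 (0.65 to 0.97) with 18 called without low 3 and low 4, and without the arrays with Y-linked signal 0.78 (0.63 to 0.95) with 3 called.

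The list of double-stranded RNA sensing, a subject of the laboratory's own work, had 9 of 16 measured members higher, 0 lower and a median of 0.57 (0.18 to 0.93), with 12 higher adjusted over the list alone. Ddx58, which encodes the RNA sensor RIG-I, was 0.85 ± 0.10 higher, Dhx58 0.93 ± 0.13, Zbp1 1.00 ± 0.15 and Oasl2 1.13 ± 0.17. All of these are also known as interferon-induced. Camera gave an adjusted p of 9.0e-10, and the adjusted p = 0.205 with an estimated correlation. The median was 0.54 with 7 called without low 3 and low 4, and without the arrays with Y-linked signal 0.47 (0.16 to 0.77) with 0 called.

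Hair shaft and inner root sheath genes fell as a group, with 19 of 38 measured members lower, 0 higher and 31 lower adjusted over the list alone. The median change was -1.52 (-1.90 to -1.06). Krt75, a companion layer keratin, fell by 1.91 ± 0.20 (SE) and Padi3, an enzyme that modifies hair proteins, by 1.49 ± 0.18. Camera gave an adjusted p of 1.6e-25, and the adjusted p = 0.217 with an estimated correlation. The list's mean ranged from 8.93 in low 3 to 10.49 in low 2 and from 7.90 to 8.50 in the high group. Without low 3 and low 4, 33 members were lower and the median was -2.17, and without the arrays with Y-linked signal 0 were called and the median was -1.19 (-1.56 to -0.83).

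The melanocyte and pigmentation list had 12 of 18 members lower (15 adjusted over the list alone) and all 18 estimates negative, with a median of -0.67 (-1.10 to -0.49). Slc24a5, an ion exchanger of pigment granules, fell by 1.36 ± 0.15 and Pmel, a structural protein of these granules, by 1.05 ± 0.14. The camera adjusted p was 4.9e-17, and the adjusted p = 0.205 with an estimated correlation. Sebaceous gland genes had 7 of 16 lower (12 over the list alone) at a median of -0.37, with Scd3 at -1.30, Elovl3 at -0.96, Mc5r at -0.93 and Fasn at -0.38 (camera adjusted p = 2.2e-09; adjusted p = 0.205 with an estimated correlation). With low 3 and low 4 left out, 1 sebaceous and 7 melanocyte genes were lower at medians of -0.37 and -0.63, and without the arrays with Y-linked signal 0 of either at -0.35 and -0.49. Without low 2 alone 2 sebaceous genes were lower, at a list mean of -0.41 against -0.44.

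The bulge and germ list, of follicle stem cell and lower follicle markers with some of the upper follicle such as Krt79, had 5 of 19 lower (10 lower and 2 higher adjusted over the list alone), at a median of -0.28 (camera adjusted p = 3.2e-05; adjusted p = 0.127 with an estimated correlation). Foxc1 was at -0.78, Krt79 at -0.70, Lhx2 at -0.68 and Tcf7l1 at -0.28. The list of Shh, Eda, Bmp and Fgf genes of follicle morphogenesis had 6 of 31 lower (17 lower and 2 higher adjusted over the list alone), at a median of -0.27. Ptch1, the receptor of Shh, fell by 0.77 ± 0.16, Fgf5 by 0.76 ± 0.15 and Bambi by 0.66 ± 0.11. Camera gave an adjusted p of 4.6e-07, and the adjusted p = 0.205 with an estimated correlation. In this list 1 member was lower without low 3 and low 4 at a median of -0.18, and 0 without high 3 at a mean of -0.27 against -0.30. With the muscle score as a covariate 0 of its members were lower, at a median of -0.17. Of the bulge and germ genes 2 were lower without low 3 and low 4 at a median of -0.32, 3 without low 1 at -0.27, and 0 without the arrays with Y-linked signal at -0.13.

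The Wnt pathway list had 4 of 39 members lower, and 6 lower and 1 higher adjusted over the list alone. The median was -0.05 (-0.10 to 0.06), and 0.0087 without the arrays with Y-linked signal. The mean was -0.11 and was negative in all alternatives (-0.17 to -0.07), with 14 of 39 estimates positive. The mean thus kept its direction, while the median lay near 0. The lower members were the secreted inhibitor Wif1 (-1.03), the transcription factor Lef1 (-0.98), the receptor Fzd7 (-0.52) and Tcf7l1. Camera gave an adjusted p of 0.0302 (0.0020 to 0.126 over the alternatives with the preset correlation), and the adjusted p = 0.486 with an estimated correlation. The Wnt list did not pass without low 1 (0.126) or high 4 (0.0748), and 2 members were lower without low 2. Cell cycle genes had 16 of 36 lower and 32 adjusted over the list alone, with a median of -0.42 (-0.50 to -0.30). Mki67, a marker of dividing cells, fell by 0.86 ± 0.14 (SE), and Ccnb2, Cenpf and Ccna2 by 0.57, 0.57 and 0.50. The camera adjusted p was 7.1e-22, and the adjusted p = 0.217 with an estimated correlation. Without low 3 and low 4, 0 cell cycle genes passed while the median was -0.34, and without the arrays with Y-linked signal 0 passed at -0.41. Without low 2 alone 4 passed.

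The lists of epidermal differentiation and wound-activated keratinocytes were higher by camera, with few called members. Epidermal differentiation genes had 4 of 38 higher (15 higher and 1 lower adjusted over the list alone) at a median of 0.32, with Rptn at 0.85 ± 0.19 and the protease Klk7 at 0.38 ± 0.08 (camera adjusted p = 8.9e-06; adjusted p = 0.523 with an estimated correlation). Wound-activated keratinocyte genes had 5 of 26 higher and 2 lower (12 and 4 adjusted over the list alone), at a median of 0.43. The lower ones, Sprr2a1 (-0.81) and Sprr4 (-1.08), are envelope genes like the higher Sprr2 members. Camera gave an adjusted p of 0.0151, and the adjusted p = 0.523 with an estimated correlation. The wound-activated list did not pass without high 4 (0.0748). Nor did it pass without low 3 and low 4 (adjusted p = 0.0715; 0.00030 to 0.180 over the alternatives), though its median there was 0.42. Without low 3 and low 4, 0 differentiation genes were called. The differentiation median was 0.10 without these arrays and 0.07 with the muscle score as a covariate, where the list did not pass (adjusted p = 0.135; from 5.4e-08 over the alternatives). Without low 2, 0 differentiation genes, 0 collagen genes and 1 higher wound-activated gene were called. Collagens and scar matrix had 2 of 37 higher (8 over the list alone), the collagen-modifying enzymes Plod2 (0.49 ± 0.09) and P4ha1 (0.37 ± 0.07), at a median of 0.21 (camera adjusted p = 3.2e-05; adjusted p = 0.464 with an estimated correlation). The collagen list did not pass without the arrays with Y-linked signal (adjusted p = 0.128; from 2.0e-06 over the alternatives).

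Markers of skeletal muscle, fat and nerve were also lower by camera, with few or no called genes. The skeletal muscle list had 0 of 31 called and a median of -1.28, which was -0.0023 without low 3 and low 4 (camera adjusted p = 1.3e-08; adjusted p = 0.486 with an estimated correlation). Adipocyte genes had 0 of 20 called (7 lower adjusted over the list alone) and a median of -0.40, which was -0.15 without these arrays. Their camera adjusted p was 9.8e-07, and the adjusted p = 0.266 with an estimated correlation. Their list means were 7.94 in low 3 and 8.04 in low 4, against 7.08 to 7.39 elsewhere. The Schwann cell list had 2 of 11 lower (4 over the list alone), Pmp22 (-0.47) and Mbp (-0.40), both proteins of myelin (camera adjusted p = 0.00315; adjusted p = 0.275 with an estimated correlation), and 0 called without low 2.

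Immune lists held few called genes. B and plasma cell genes had 1 of 12 higher, Cd22 at 0.40 ± 0.08 (4 over the list alone; camera adjusted p = 0.00392; adjusted p = 0.304 with an estimated correlation), and 0 without low 2. MHC genes had 0 of 18 called (4 higher and 1 lower over the list alone; camera adjusted p = 0.00286; adjusted p = 0.523 with an estimated correlation), and the list did not pass without low 3 and low 4 (adjusted p = 0.193; from 3.2e-05 over the alternatives). IL-6 and STAT3 signalling had 0 of 14 called (1 over the list alone; camera adjusted p = 0.0148; adjusted p = 0.455 with an estimated correlation), and did not pass without high 2 (adjusted p = 0.0696; from 0.0022 over the alternatives). Inflammatory cytokines did not pass as a list (adjusted p = 0.0642; 0.0107 to 0.320 over the alternatives). They passed in 11 of 23 alternatives, among them without low 3 (0.0127), high 1 (0.0264), high 3 (0.0257) or high 4 (0.0453). They had Il1f9 (1.13), Il1f6 (1.20), both IL-36 cytokines, and the chemokine Ccl3 (0.47) higher and the chemokine Cxcl12 (-0.61) lower, with 5 higher and 1 lower over the list alone. A row that Il1f9 shares with Cwc22, left out of the gene-level tests, was at -0.62 and did not pass. Macrophage genes had Fcgr1 higher (0.67) and Fcgr3 lower (-0.77), receptors for antibodies, at a list adjusted p of 0.369, which was 0.00906 without low 3 and low 4 (0.00906 to 0.900 over the alternatives). T and natural killer cell genes had Cd4 higher (0.59) and Thy1 lower (-0.58) at 0.530.

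The prostaglandin list did not pass (adjusted p = 0.591). Its Ptges (0.58) rose, and Ptgds (-0.52), Pla2g2e (-0.71) and Ptger3 (-0.80) fell. The list of endothelium, lymphatics and other vessel markers had Rgs5 (0.71) and Emcn (0.40) higher and Prox1 (-0.43) and Cspg4 (-0.33) lower (list adjusted p = 0.0940). Prox1 was the mean of 2 rows that differed in size, at -0.78 and -0.08. Dermal papilla genes had Inhba (0.75) and Cxcr4 (0.55) higher and Hhip (-1.05) and Wif1 lower (0.139). Single called genes were Itga6 (-0.49) of the basal keratinocyte list (0.435), Timp3 (-0.74) of the metalloproteinase list (0.679) and Egr2 (-0.61) of the immediate early list (0.0642), and the myofibroblast list (0.995) held Inhba and Thy1. The 2 rows of Itga6 were at -0.82 and -0.16. No members were called in the lists of neutrophils (0.722), mast cells (0.0940), dendritic and Langerhans cells (0.369), red blood cells (0.422), retinoid genes (0.331), circadian clock (0.221) and sex-linked genes (0.426). Some of these lists passed in alternatives: the immediate early list in 11 of 23, among them without low 3 (0.0065) or high 1 (0.0017), endothelium in 5, among them without high 2 (0.0332), dermal papilla in 1, mast cells without low 2 (0.0284) or high 1 (0.0053), and the circadian clock over all rows (0.0152) and without high 2 (0.0356). The median and the mean differed in sign in the prostaglandin (0.05 and -0.05), basal keratinocyte (0.01 and -0.0069) and metalloproteinase (0.12 and -0.04) lists. In the myofibroblast list camera pointed down while the median was 0.05.

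By camera 18 of the 35 lists passed, 8 higher and 10 lower, and 0 passed with an estimated correlation, where the smallest adjusted p was 0.127. The exact two-sided permutation test of 4 against 4 arrays cannot give a p below 0.0286. The means of 15 lists reached it by not overlapping between groups, and after adjustment over the lists 0 passed, at a smallest adjusted p of 0.0667. The fry p of the called lists was at most 0.162.

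**Figure D3:**
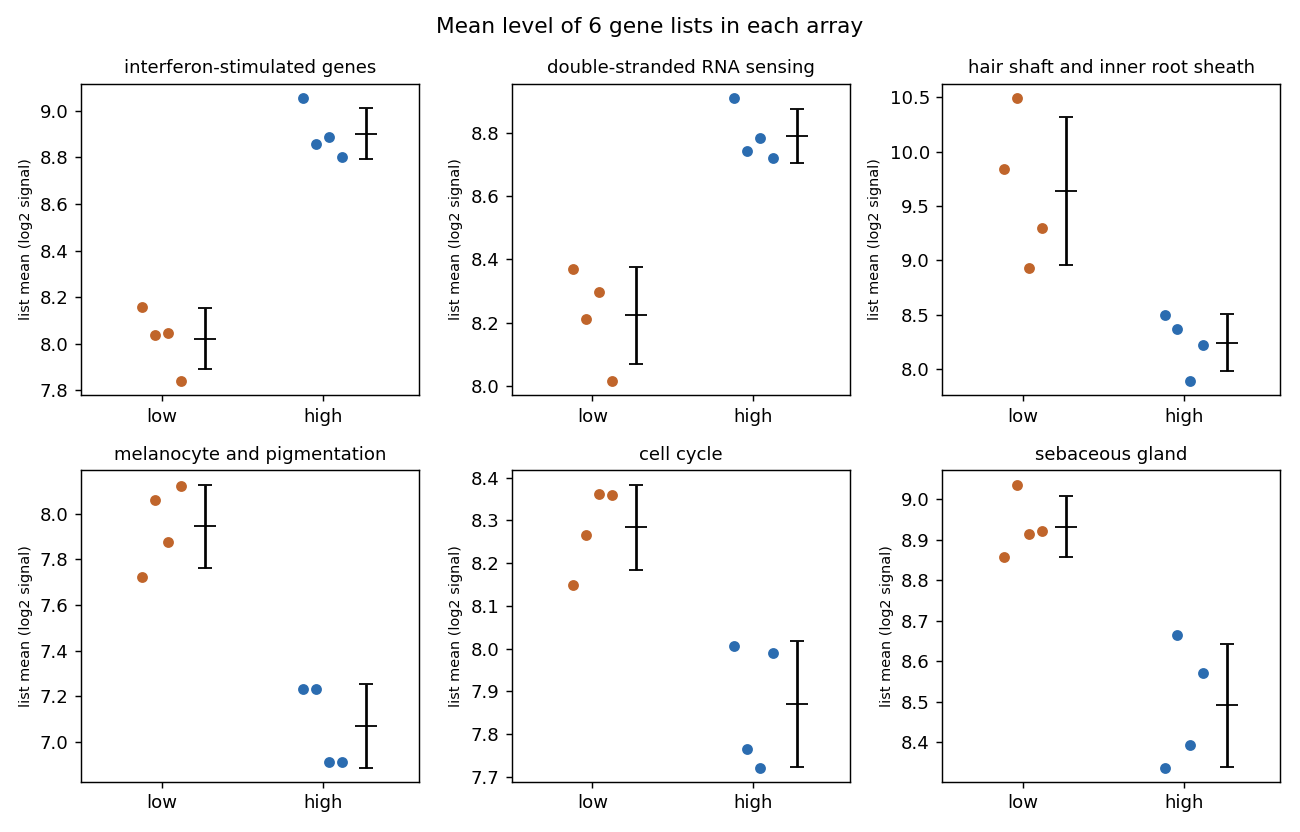
Mean log2 signal of the measured members of 6 gene lists in each array, a point per array, with a black bar for the group mean and whiskers for the SD of 4 arrays. The interferon-stimulated list mean lies between 7.84 and 8.16 in the low arrays and between 8.80 and 9.06 in the high arrays.

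Of the 14 candidate genes reported, 3 were called. Shh, the signal that starts follicle growth, fell by 1.00 ± 0.21 (SE; adjusted p = 0.0373), Lef1 by 0.98 ± 0.16 (0.0128) and Ptgds, a prostaglandin D2 synthase, by 0.52 ± 0.10 (0.0232). Shh did not pass when any array but low 1 was left out, at adjusted p up to 0.107 without high 3 (0.0246 to 0.257 over all alternatives). Its values were 7.60 in low 1 and 7.68 in low 2, and 8.06 and 8.55 in the muscle-rich low 3 and low 4, against 6.63 to 7.22 in the high arrays. Part of its fall thus went with the muscle-rich arrays. Ptgds did not pass without low 2, low 4, high 2, high 3 or high 4 (at most 0.0658; 0.00963 to 0.351 over all alternatives). Lef1 passed without any single array (at most 0.0456; 0.00634 to 0.184 over all alternatives). The RNA sensor Tlr3 was at 0.22 ± 0.09 (0.194), Il6 at 0.03 ± 0.20 (0.950) and Stat3 at 0.10 ± 0.06 (0.396), none past the threshold. Krt15 (-0.74 ± 0.21, 0.0823) and Edar (-0.31 ± 0.08, 0.0678) did not pass either, though Krt15 passed without high 2 (0.0217; 0.0217 to 0.491 over all alternatives) and Edar after quantile normalization, median centring and cyclic loess (0.0241 to 0.468 over all alternatives). Not past the threshold in any alternative were Krt17 (-0.26), Gli2 (-0.19), Ptgdr2 (0.27), Fgf9 (0.13), Wnt7b (0.12) and Krt5 (0.05). The estimates of Il6 and Krt5 were negative after quantile normalization, median centring and cyclic loess.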

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

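The tests of other cell types, of sex in the interferon and hair shaft lists, separate strain variants, biopsy depth and content and mixed sexes were chosen after the result was seen, and those of other splits of the arrays and of sex as the source of the calls before it. A sample far from the other 3 of its group was found in 5 of 146 checks of named genes and list means, and chance gives about 1 in 20. Retnla was at 5.49 in high 2, against 4.49 to 4.56 in the other high arrays. Stat3 was at 9.08 in high 4 against 9.11 to 9.12, and Krt15 at 9.64 in low 1 against 9.84 to 9.87. The mean of the immediate early and heat shock list was 9.07 in low 3 against 8.90 to 8.92, and 8.83 in high 1 against 9.15 to 9.21. Among the 87991 rows with no gene listed, which the comparison left out, 80 were higher and 124 lower in high regeneration (limma, adjusted p under 0.05), and 9275 had an unadjusted p under 0.05.

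Of the 35 splits of the 8 arrays into 4 and 4, only the real split, 1 of 35, gave as many genes in either direction. It gave 376 higher and 500 lower, and the highest of the others gave 2. Mixed splits carry the difference between the groups as spread within theirs, which lowers their counts. A share of 1 of 35 is also the smallest these splits can give. The gene counts therefore argue against chance but do not exclude it. For the gene lists chance stays open: 5 of the 35 splits called at least the 18 lists of the real one, and the highest other called 21. That split set low 1, low 2, low 4 and high 4 against the rest. It and the other splits with 18 or more lists exchanged 1 array between the groups, and splits with 2 arrays of each strain on either side called at most 14.

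Of 27 interferon-stimulated genes measured, 22 were higher and all 27 had positive estimates, at a median of 0.84 (0.70 to 0.96), and the 22 called ones lie on 11 chromosomes. More immune cells of every kind in the high-regeneration biopsies would raise immune markers alike, but the highest median among 6 immune lists was 0.18 (0.07 to 0.35), in B and plasma cells. That list lay at means of 6.53 to 6.96, near the array medians of 6.09 to 6.29, where a rise may be hard to see. Macrophage genes, at means of 8.44 to 8.79, had a median of 0.13 (-0.05 to 0.22), with Fcgr1 higher (0.67) and Fcgr3 lower (-0.77). A shift between kinds of immune cells can cancel in a median and stays open. A lower share of follicle tissue would raise the markers of every other tissue alike. Among endothelium, macrophages and collagens, the lists compared, the highest median was 0.21 (0.13 to 0.29), in collagens. Epidermal lists were not part of that test and went further, to 0.43 (0.12 to 0.87) in wound-activated keratinocytes, so a change in the epidermis itself stays open. Separate strain variants in each gene would not all point up: all 22 called members were higher, against 42.9% of all called genes (exact one-sided binomial test, p = 8.3e-09), which takes members as independent, as separate variants would be. A stronger interferon response in the high-regeneration group may remain as a hypothesis, and whether strain, exposure or wound stage set it was not tested.

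Of 38 hair shaft and inner root sheath genes 19 were lower in high regeneration. Deeper low-regeneration biopsies with muscle and fat may be asked about first, but without the muscle-rich arrays the hair shaft median was -2.17 (upper bound -1.65), further from 0 than with them. Hair-bearing skin beside the scar in the low-regeneration biopsies cannot be told apart from a strain difference, since the medians of the 4 lists compared (hair shaft, bulge and germ, sebaceous gland, melanocyte) were all negative, the least so at -0.28 in bulge and germ. The dermal papilla list, not part of that test, had a median of -0.04 (-0.29 to 0.03) and did not pass. Strain and biopsy are confounded here. Differences in coat colour, hair cycle or wound closure between the strains stay open and were not tested.

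Low 2 and low 4 had both Xist and Y-linked transcripts. Their Xist levels were 10.6% and 14.5% of that of the 5 arrays without Y-linked signal, and the nearest lay 2.78 log2 units from the level of either sex. Eif2s3y was at 7.67 and 7.57 and Uty at 6.61 and 6.72. RNA of both sexes in these samples is a candidate explanation, and pooling and carry-over were not told from each other. In that case these arrays may not each stand for a single mouse, while all tests and SDs treat them so. A sex difference as the only source of the interferon and hair shaft changes is argued against by the 5 arrays without Y-linked signal. The median of interferon-stimulated genes there was 0.78 (0.63 to 0.95) and that of hair shaft genes -1.19 (-1.56 to -0.83), with intervals over members and not over mice. Interferon list means were 8.16 in low 1 and 8.05 in low 3, against 8.86 to 9.06 in these high arrays. Hair shaft list means were 9.84 and 8.93, against 7.90 to 8.50. Low 3 was muscle-rich, and with 2 low and 3 high arrays a part played by sex is not excluded. The wound-activated keratinocyte, collagen, Wnt and IL-6 lists did not pass there (camera adjusted p of 0.180, 0.128, 0.126 and 0.0687). Their medians were 0.22, 0.10, 0.0087 and 0.15, against 0.43, 0.21, -0.05 and 0.14 in all arrays, so the IL-6 median did not shrink. The bulge and germ list passed, at a median of -0.13 against -0.28. For these lists sex stays open, and a call lost with fewer arrays does not by itself point to it. Whether sex is a source of single calls stays open. With the Xist level as a covariate 100% of the called genes kept at least 0.5 of their change, but Xist averaged 11.33 in low and 11.16 in high regeneration, so the covariate could hardly move a group difference and tests nothing. In the 5 arrays without Y-linked signal 5 genes were higher and 10 lower, a count that fewer arrays lower by themselves.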

How the results depend on the processing

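The settings on muscle, Xist and Y-linked arrays were chosen after seeing the data. Over the alternatives, called genes named here kept direction and call in 1691 values, lost the call in 507 and changed direction in 0; called lists did so in 393, 37 and 0. The replicate numbers do not pair the samples: same-numbered arrays correlated in their deviations at -0.08, 0.02, -0.26 and -0.10, and no array correlated best with its own number. With the replicate block 105 genes were higher and 134 lower and 1 candidate passed. After median centring 212 were higher. Higher and lower counts were 164 and 228 over every row (0 candidates and 15 of the 24 named genes passed), 43 and 69 at a log2 change of at least 1 (0 candidates), and 798 and 994 at an adjusted p under 0.1 (5 candidates). They were 127 and 198 without the muscle-rich arrays (14 named genes), 117 and 217 with the muscle score (1 candidate), and 5 and 10 without the arrays with Y-linked signal (0 candidates, 4 named genes), where fewer arrays remain. With an estimated correlation 0 lists passed. Leaving out single arrays gave 129 to 536 higher, 163 to 669 lower, 1 to 3 candidates, 17 to 23 named genes and 17 to 21 lists. The cause was not tested. The alternative pseudocounts were not run because the values are on a log2 scale, and the muscle list has no value with its own mean as covariate.

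All 52 changes of sign were of values that did not pass in the main comparison. Il6 was at -0.043 after quantile normalization, -0.039 after median centring, -0.052 after cyclic loess, -0.031 without the muscle-rich arrays, -0.073 with the muscle score, -0.065 without the Y-linked arrays and from -0.17 to 0.13 without single arrays. In these settings except the last, Krt5 was at -0.041, -0.010, -0.033, -0.023, -0.033 and -0.011. Mean changes of lists turned as follows. Median centring gave -0.052 for the myofibroblast and TGF-beta response list and -0.021 for macrophages and monocytes, and cyclic loess -0.010 for myofibroblasts. Array weights gave 0.049 for metalloproteinases, 0.098 for neutrophils and 0.0041 for mast cells. Genes at or above the median level gave 0.0098 for dermal papilla, 0.052 for metalloproteinases, 0.19 for neutrophils and -0.00042 for T cells, and the 25th percentile gave 0.023 for neutrophils. The brightest row gave 0.011 for basal keratinocytes. Without the muscle-rich arrays the means were 0.0024 for prostanoids, 0.042 for metalloproteinases, 0.22 for neutrophils, 0.070 for mast cells and 0.022 for red blood cells, and with the muscle score 0.031, 0.22, 0.046 and 0.032 for the last 4. Without the Y-linked arrays they were -0.093 for myofibroblasts, -0.0011 for macrophages and 0.011 for red blood cells. Without single arrays they ran from -0.029 to 0.046 for myofibroblasts, -0.014 to 0.10 for macrophages, -0.089 to 0.010 for metalloproteinases, -0.14 to 0.078 for neutrophils, -0.024 to 0.0099 for basal keratinocytes and -0.0038 to 0.12 for dendritic cells. The cause was not tested. Low signal over background limits dim genes such as Il6, whose mean was 4.96 in low regeneration.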

Other observations

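The genes named here and the test of neighbours called in opposite directions were chosen after the result was seen, and the test of neighbours called in the same direction before it. No test of a gene family or pathway was made for these genes. Among the called genes were the kallikrein proteases Klk9 at 1.35 ± 0.29 (SE; limma, adjusted p = 0.0373), Klk13 at 0.72 ± 0.16 and Klk8 at 0.66 ± 0.12, beside Klk7 at 0.38 ± 0.08. The IL-36 cytokine Il1f8 was at 0.83 ± 0.16, with Il1f6 at 1.20 ± 0.25 and Il1f9 at 1.13 ± 0.13 in the row paired with it alone. The epidermal proteases Tmprss11a and Tmprss11g were at 1.38 ± 0.24 and 1.40 ± 0.27. Ifnk, a type I interferon of keratinocytes, was at 1.11 ± 0.15 from a low level of 4.95 in low regeneration. Hk2 was at 0.86 ± 0.17 and Pfkfb3 at 0.50 ± 0.06. The metallothioneins Mt1 and Mt2 were at -0.54 ± 0.08 and -0.57 ± 0.09. Ube2l6, an enzyme that conjugates the interferon-induced protein ISG15, was at -1.82 ± 0.15 as the mean of 3 rows (adjusted p = 0.00101). These ran from -3.23 to 0.74, and the rows it shares with another gene were at 0.45 without passing (adjusted p of 0.0545 and 0.0568), so no direction can be given for it. Among the 2300 rows that pair with several genes, 45 were higher and 27 lower.

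Calls lay next to each other in the genome. After leaving out keratin, cornified envelope and several interferon gene families, the last of which were not part of the test as first written, 46 pairs of neighbouring genes among 19877 were called in the same direction, against a mean of 17.0 in 1000 random placements (10 to 25, at most 31; permutation p = 0.001, the smallest they can give). Haplotype blocks that differ between the strains may give such pairs. Pairs called in opposite directions numbered 14 against a random mean of 16.1 (9 to 24). Linked variants that act on each gene separately would raise both counts alike. The values argue against such variants as the only source of the same-direction pairs, but a count within the random range cannot exclude a smaller share. Many of the 46 pairs are related genes or share regulation, such as Klk8 and Klk7, Il1f9 and Il1f6, Mt2 and Mt1, and Rsad2 and Cmpk2, and shared regulation of neighbours, which the test does not separate from haplotype blocks, stays open.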
